A study of Mus musculus with 12 samples.

How the data were processed

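Gene expression was measured with single-colour arrays in 12 samples of mouse bone marrow cells. Per the labels' protocols, bone marrow of Nfat5 +/+ Vav-Cre mice (wild-type) or Nfat5 fl/fl Vav-Cre mice (NFAT5-deficient) was transplanted into irradiated wild-type recipients. Donor and recipient cells carried different alleles of CD45. At 13 weeks after transplantation, donor-derived hematopoietic stem cells (HSC, CD48-negative and CD150-positive) and multipotent progenitors (MPP, CD48-positive and CD150-negative) were sorted. Both gates lie within the lineage-negative, Sca-1-positive, Kit-positive compartment. Per the labels' protocols, 300 pg of total RNA per sample was amplified and biotin-labelled with the NuGEN Ovation One-Direct system. The design held 4 groups of 3 arrays each, 1 group per genotype and population.

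The authors deposited 1 table of log2 intensities, with 1 value per probe set and array. The submitters' processing notes name RMA and limma without versions and without the role of each. The log2 scale was read from the deposited values, which ran from 2.51 to 13.28. Scanner files, detection calls and scan dates were not used here, and no technical batch could be tested. The probe annotation version and genome build were not given in the sources used here, and no coordinates were printed. For arrays, their number limits the precision.

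The table held 22142 probe sets. Of these, 19527 had 1 gene symbol in the platform annotation, 0 had several, and 2615 (11.8%) had no name there and were kept out of the named tests. All 19527 symbols were looked up by Entrez identifier, and 0 changed. Where a gene had more than 1 probe set (33 genes), the probe set with the highest mean over the 12 arrays stood for it, which left 19494 genes. No further normalization and no filter on dim genes was applied.

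Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with a mean for each of the 4 groups over the 12 arrays and an intensity-dependent variance prior. P-values were adjusted with the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were NFAT5-deficient minus wild-type in HSC and in MPP, the difference between these effects (interaction), and HSC minus MPP in each genotype. For 28 gene lists, limma's camera was used with a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and limma's fry beside it. Single values were compared with exact two-sided permutation tests. Fry is a rotation test of whether the genes of a list move on balance one way.

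The design, the lists, the rule for naming genes and the settings to vary were fixed before the data were examined. The named genes were Nfat5, up to 10 genes with the largest rise and 10 with the largest fall among those called, and, per list, up to 4 called members. Where fewer than 10 passed in a direction, genes with the smallest unadjusted p filled up to 6. Where no member of a list passed, the 2 members with the smallest unadjusted p were taken. Unnamed gene models and olfactory receptors were left out of the largest changes.

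The fit and the list test were tested on simulated data with known changes, made from the arrays' own residuals over 19494 genes in 10 simulations per comparison. In the simulation of the HSC genotype comparison, 14.3% of genes with a level above 7 and a change of 1 on the log2 scale were called, 56.6% at a change of 2 and 87.4% at a change of 4. No run without a change gave a false call (0 of 10 simulations) in that comparison. Of 10 lists shifted by 0.5, 9 were called, with 2 calls among lists that had not been shifted. Residuals were shuffled gene by gene, which removes shifts that genes of an array share. These runs therefore cannot bound false calls of genes or lists on real arrays. There, 3 other splits of the HSC arrays gave calls, up to 5 genes. Many genes changed in each run, which eases the adjustment for each.

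The settings varied were a filter on dim genes, eBayes without the trend, robust eBayes, fits of only the groups compared, centring and quantile normalization, array weights, the mean of a gene's probe sets, the array number as a block, other thresholds, and leaving out each array in turn. Comparisons that pooled genotypes or populations, and a fit without the outlying HSC arrays (wild-type 66 and NFAT5-deficient 70), were added after seeing the data. Those arrays lay at the ends of the second principal component (58.1 and -42.8). By spread around the group means, array 70 did not stand out (residual SD 0.519, against 0.542 and 0.539 for wild-type HSC arrays 67 and 75). Drawings were made with Python 3.11.15 and matplotlib 3.10.9.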

Results

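The study measured how loss of NFAT5, a transcription factor best known for the response to hypertonic stress, changed gene expression in blood stem and progenitor cells regenerating the marrow after transplantation. Its arrays covered HSC and MPP of wild-type and NFAT5-deficient donors, with 3 arrays per group. Each array is named by its group and its sample number: 66, 67 and 75 for wild-type, and 64, 70 and 76 for NFAT5-deficient cells. Within groups, arrays correlated across genes at 0.898 to 0.912 in wild-type HSC and 0.920 to 0.937 in NFAT5-deficient HSC. In MPP the range was 0.924 to 0.935 in wild-type and 0.948 to 0.952 in NFAT5-deficient cells. Arrays of different genotype correlated at 0.896 to 0.933 in HSC and 0.932 to 0.949 in MPP. These ranges overlapped those within groups, so the correlations did not set replicates apart by genotype.

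Nfat5 itself was lower on NFAT5-deficient arrays, with residual signal in every sample. In HSC its log2 intensity was 9.49 ± 0.29 (SD, n = 3) in wild-type and 8.24 ± 0.58 (SD, n = 3) in NFAT5-deficient cells, a difference of -1.25, or 42.1% of the wild-type level. The 3 wild-type arrays (9.81, 9.38 and 9.27) all lay above the 3 NFAT5-deficient arrays (8.76, 8.34 and 7.62), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. In MPP the level was 8.58 ± 0.41 in wild-type and 7.92 ± 0.42 in NFAT5-deficient cells (SD, n = 3 each), a difference of -0.66, or 63.2%, with an exact permutation p of 0.2. There the groups overlapped, since NFAT5-deficient array 76 read 8.40 and wild-type array 75 read 8.12. Over both populations the difference was -0.96, with an exact stratified permutation p of 0.01 (smallest possible 0.005), counting HSC and MPP arrays as separate samples. Nfat5 was represented by 1 probe set, whose place relative to the deleted part of the gene is not given in the sources used here. The residual signal therefore does not measure how completely the gene was deleted.

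**Figure D1:**
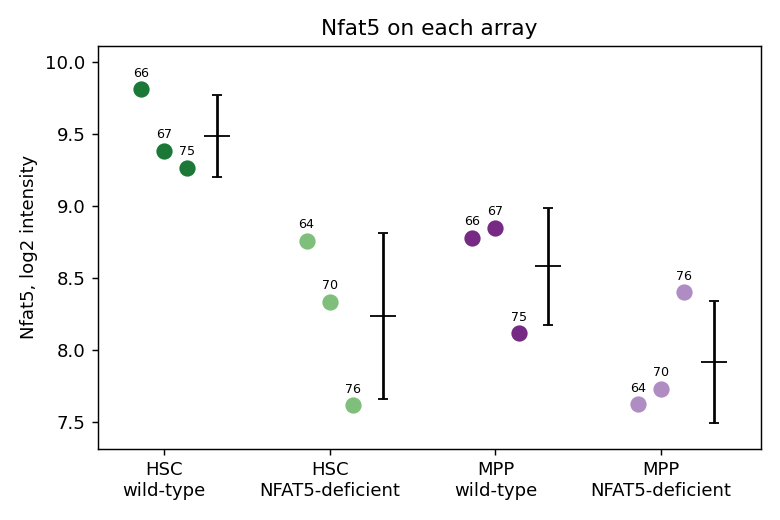
Nfat5 log2 intensity (vertical axis, which does not start at 0) on each array of the 4 groups (horizontal axis). Points are arrays labelled by sample number and bars are the group mean with the SD over 3 arrays; in HSC the wild-type arrays sit above the NFAT5-deficient arrays, and in MPP the groups overlap.

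The sorting markers separated HSC from MPP in both genotypes, which follows largely from the gates, here and wherever these markers count below among calls. Slamf1, which encodes CD150, was 9.84 ± 0.24 in wild-type HSC and 6.26 ± 0.14 in wild-type MPP (SD, n = 3), and 10.08 ± 0.74 against 6.46 ± 0.42 in NFAT5-deficient cells. Cd48 was 6.48 ± 1.25 in wild-type HSC and 9.92 ± 0.67 in wild-type MPP, and differed by -3.78 between HSC and MPP of NFAT5-deficient cells. Kit, the stem cell factor receptor shared by both gates, lay between 11.16 and 11.43 in the 4 group means. The Y-linked genes Eif2s3y, Kdm5d and Uty had group means between 3.65 and 5.07 in every group.

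In wild-type cells, HSC differed from MPP through stem cell and megakaryocyte genes, higher in HSC, and lymphoid priming and replication genes, lower in HSC. Dntt, the terminal transferase of lymphoid progenitors, fell by 6.59 on the log2 scale in HSC (SE 0.28, limma adjusted p = 3.3e-06). Satb1, a chromatin organizer active in lymphoid development, was lower by a log2 value of -4.43, the granule protease gene Ctsg by -4.24 and the receptor gene Flt3 by -2.70. Slamf1 rose by 3.58 (SE 0.36), Nupr1 by 4.41, Tek, the angiopoietin receptor gene, by 3.42, and Pf4, which encodes platelet factor 4, by 2.55. The largest other rises among named genes were Pdzk1ip1 (3.22), Gbf1 (3.16), Clec1a (3.12) and Klf12 (2.96), and further falls were Atp8b4 (-5.17), Cd53 (-3.14), Ska3 (-2.48), Il10rb (-2.47), Cst7 (-2.36) and Plac8 (-2.36). Dntt and Atp8b4 read 4.44 and 4.74 in wild-type HSC and Tek 4.99 in wild-type MPP, within the range of the Y-linked genes, and no detection calls were used, so the size of these differences is not resolved. Klf12 read 5.19 in wild-type MPP, just above that range, so the size of its rise may not be resolved either. limma called 32 genes of 19494 tested, 15 higher and 17 lower in HSC.

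By list, the HSC genes rose in wild-type HSC (23 measured, median log2 0.71, limma's camera). Of these, 4 passed over all genes (Slamf1, Tek, Pdzk1ip1 and Clec1a) and 10 adjusted over the list alone, all higher. The MPP and lymphoid priming genes fell (16 measured, median -1.30), with 5 members past the test over all genes, Dntt, Satb1, Cd53, Flt3 and Cd52, and 10 adjusted over the list alone. Megakaryocyte and platelet genes rose (16 measured, median 0.64), with Pf4 past the test over all genes and 6 members adjusted over the list alone. G1/S and replication genes fell together (21 measured, 18 with a lower value, median -0.33), with 0 members past the test over all genes and 2 adjusted over the list alone, Mcm4 (-1.31) and Mcm5 (-0.96). The same 4 lists passed with an estimated correlation. In both genotypes, the HSC list and the MPP and lymphoid priming list kept their calls without the sorting markers Slamf1 and Cd48.

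A further 4 lists fell in wild-type HSC under the preset correlation and lost the call with an estimated one. G2/M genes had a median of -0.37, with 21 of 23 members lower (adjusted p = 0.325 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.14 (adjusted p = 0.119 with an estimated correlation). For interferon induction and sensing genes the median was -0.28 (adjusted p = 0.0918 with an estimated correlation). Of their 16 members, 0 passed over all genes and 3 fell when adjusted over the list alone: Tlr7 (-3.09, to a level of 4.46 within the range of the Y-linked genes), which encodes an endosomal RNA sensor, Cgas (-1.14), which encodes a cytosolic DNA sensor, and Sting1 (-1.13), its adaptor gene. Neutrophil and granule genes had a median of -0.16 (adjusted p = 0.362 with an estimated correlation), with Ctsg and Elane (-2.08) past the test over all genes and 3 members adjusted over the list alone. Among them Mpo read 7.48 ± 0.57 in wild-type HSC and 11.76 ± 0.17 in wild-type MPP, Prtn3 8.01 ± 0.19 and 8.15 ± 0.20, and S100a9, abundant in mature neutrophils, 9.16 ± 2.43 and 9.50 ± 1.18 (SD, n = 3).

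The oxidative phosphorylation, interferon sensing and neutrophil lists also lost their calls without wild-type MPP array 67 or HSC array 75, and the neutrophil list without HSC array 66. The neutrophil median ran from -0.58 without HSC array 67 to 0.14 without HSC array 75, so its sign depended on single arrays. The interferon sensing median shrank to -0.07 without MPP array 67, and without HSC array 75 the oxidative phosphorylation and G2/M medians shrank to -0.09 and -0.24. Leaving out wild-type MPP array 75 left 11 calls and leaving out NFAT5-deficient MPP array 76 left 18. The count was 20 without wild-type MPP array 66, 21 without wild-type MPP array 67 and 21 without wild-type HSC array 66. The calls of Dntt, Atp8b4, Nupr1, Slamf1 and Plac8 held whichever array was left out, 5 of 21 named calls. With only the wild-type groups fitted, 9 genes were called.

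In NFAT5-deficient cells many of the same genes separated HSC from MPP. Dntt fell by 6.98 in HSC (SE 0.28, limma adjusted p = 1.8e-06), Satb1 by a log2 value of -5.59, Ctsg by -4.42, Cd48 by -3.78 and Flt3 by -3.04. Nupr1 rose by 3.85, Slamf1 by 3.62 (SE 0.36), Tek by 3.04, Mmrn1, which encodes multimerin, by 2.83, and Apoe, the apolipoprotein E gene, by 2.45. Other named rises were Abcg3 (3.01), Clca3a1 (2.88), Ces2g (2.68), Slc6a15 and Ptn, and other falls were Atp8b4 (-4.92), Tespa1 (-4.37), Cst7 (-3.00), Atp1b1 (-2.68), the carbonic anhydrase gene Car1 (-2.63) and Nkg7 (-1.74). Dntt (4.38), Atp8b4 (4.94) and Fcnb (5.06) in HSC, and Abcg3 (4.95) and Slc6a15 (5.02) in MPP, lay within the range of the Y-linked genes, so the size of their differences is not resolved either. Ctsg in HSC (5.24) lay just above that range, so the size of its fall may not be resolved. limma called 41 genes, 18 higher and 23 lower.

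HSC genes rose in NFAT5-deficient HSC (median 0.89), with 4 of 23 members higher over all genes and, adjusted over the list alone, 9 higher and 1 lower (Vldlr, -1.58). MPP and lymphoid priming genes fell (median -1.18; 6 of 16 over all genes, 9 adjusted over the list alone). Megakaryocyte and platelet genes rose (median 0.39), with Pf4 (2.43) and Rab27b (1.54) past the test over all genes and 4 adjusted over the list alone. G1/S and replication genes fell (median -0.32, 17 of 21 lower, 0 members past either test). Neutrophil and granule genes fell (median -0.73), with Ctsg and Fcnb (-1.27) past the test over all genes and 5 adjusted over the list alone. Of the mature neutrophil genes, S100a9 passed adjusted over the list alone (6.04 ± 0.58 in HSC and 9.19 ± 0.28 in MPP, SD, n = 3), and the others did not. S100a8 (5.35 and 7.77), Ngp (5.97 and 6.95), Retnlg (4.87 and 5.53) and Lcn2 (5.11 and 5.63) read lower in HSC, whereas Ltf (5.61 and 5.74), Camp (6.29 and 6.49), Mmp8 (4.35 and 4.41) and Mmp9 (5.77 and 5.66) were nearly level. Of these, Retnlg and Mmp8 reached the range of the Y-linked genes. Interferon induction and sensing genes fell (median -0.29), with 0 members over all genes and 5 adjusted over the list alone, among them Tlr7 (-2.70, at 4.68 in HSC within that range) and Sting1 (-1.29). These 6 lists also passed with an estimated correlation. G2/M genes (median -0.46, 20 of 23 lower) and mast, basophil and eosinophil genes (median -0.29) fell as well, but had adjusted p = 0.137 and 0.156 with an estimated correlation.

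The mast cell list lost its call without NFAT5-deficient MPP array 64, HSC array 64 or HSC array 70, or wild-type MPP array 67, and its median shrank to -0.08 without NFAT5-deficient MPP array 64. The G2/M median ran from -0.73 without MPP array 70 to -0.22 without HSC array 70. The gene count fell to 5 without NFAT5-deficient MPP array 64, 6 without HSC array 76, 9 without MPP array 76, 11 without HSC array 70, 15 without MPP array 70 and 24 without HSC array 64. It also fell without wild-type arrays: to 17 without MPP array 67, 20 without HSC array 67 and 27 without MPP array 75. Only the calls of Dntt, Atp8b4 and Slamf1 held in every such fit, 3 of 25 named calls. With only the NFAT5-deficient groups fitted, 12 genes were called and Slamf1 lost its call.

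Across genotypes, 17 genes were called in both population comparisons, 8 higher and 9 lower in HSC. These comparisons share no array, but each gene's spread was estimated once for both, so the overlap has no simple chance value. Of the 56 genes called in either, 51 had the same sign in both. Across all genes, which are not independent replicates, the HSC minus MPP differences of the genotypes correlated at a Pearson r of 0.363. The groups did not overlap for 12.3% of genes in wild-type and 16.9% in NFAT5-deficient cells, where chance gives 10%. NFAT5-deficient replicates varied less (median gene SD 0.217 in HSC and 0.196 in MPP, against 0.247 and 0.233 in wild-type). That alone can raise the share, so the shares do not compare the size of the population difference between genotypes.

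**Figure D2:**
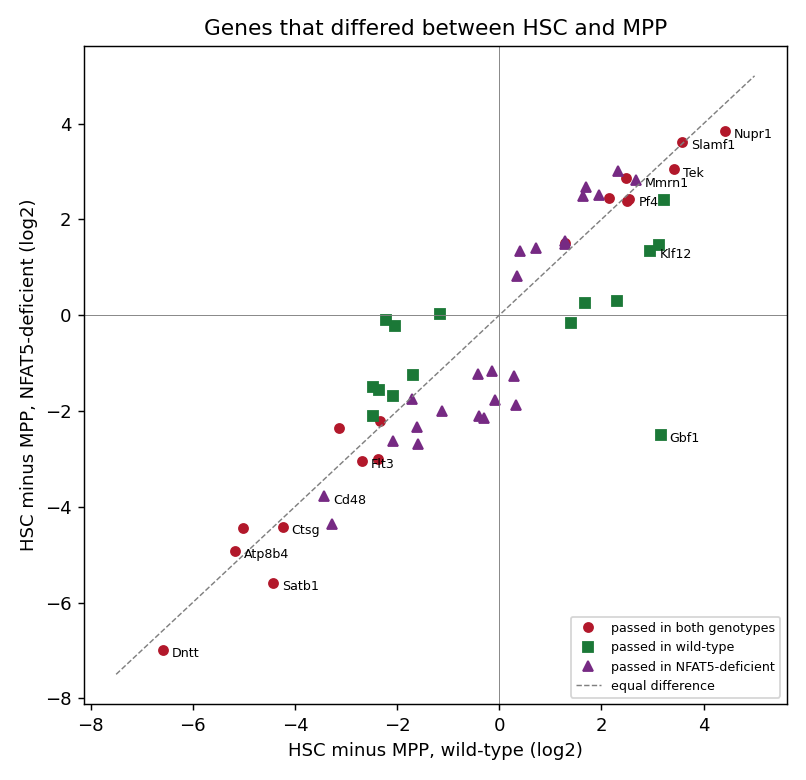
HSC minus MPP log2 difference in wild-type cells (horizontal axis) and NFAT5-deficient cells (vertical axis) for the 56 genes called in either, each from group means of 3 arrays and with symbols that show the genotype in which a gene passed. Most genes lie near the dashed line of equal differences, with Gbf1 positive in wild-type and negative in NFAT5-deficient cells.

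In HSC, no gene passed the test for loss of NFAT5. limma called 0 of 19494 genes (smallest adjusted p 0.573), and 1205 genes had an unadjusted p under 0.05 where chance gives 974.7. Of those, 522 were higher and 683 lower in NFAT5-deficient HSC. Nfat5, the targeted gene, was itself not called in HSC (limma adjusted p = 0.772) or in MPP (0.896). A missing call is therefore no evidence that a gene did not change. The HSC genes had a median difference of -0.02 and the MPP and lymphoid priming genes 0.05, with camera adjusted p of 0.921 and 0.335. The median over all genes was -0.05. Without wild-type HSC array 75 or 67 the HSC gene median was -0.0840 or -0.0056. The MPP and lymphoid priming median ran from 0.0040 without wild-type HSC array 66 to 0.137 without array 67. Over all 19494 genes, dim ones included, the median 95% confidence interval of a gene reached 0.47 log2 units to each side. That width depends on level. The median within-group SD was 0.19 for genes at 2.88 to 5.90 and 0.25 at 5.90 to 7.36. It was 0.53 at 7.36 to 9.34 and 0.34 for brighter genes. The 0.47 therefore understates the interval of a typical gene at 7.36 to 9.34.

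Type I interferon-stimulated genes, which the study's known purpose concerns, did not pass. Of 36 measured members, 22 had a higher and 14 a lower value in NFAT5-deficient HSC, with a median of 0.17 (camera adjusted p = 0.0836). With an estimated correlation the adjusted p was 0.297, and 0 members passed over all genes or adjusted over the list alone. The members with the smallest p were Slfn5 (2.11) and Ifit1 (0.81), with limma adjusted p = 0.779 for both. The G1/S and replication genes (median 0.17) also had camera adjusted p = 0.0836, with Mcm5 at 0.74 and Gins2 at 1.27, and oxidative phosphorylation genes (median 0.13) had 0.0946, which rose to 0.688 without wild-type HSC array 75, where the median was 0.00426. Osmotic stress genes, which include known NFAT5 targets, had a median of -0.11 and 8 of 10 members lower (camera adjusted p = 0.514), with Hspa1b at -0.42 and Slc6a12, a betaine transporter gene, at -0.25.

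Neutrophil and granule genes had a median of -0.34, with 13 of 16 lower in NFAT5-deficient HSC (camera adjusted p = 0.0836). S100a9 read 9.16 ± 2.43 in wild-type and 6.04 ± 0.58 in NFAT5-deficient HSC (SD, n = 3; difference -3.12, limma adjusted p = 0.779). The mean of 9 genes of mature neutrophils was 6.88 and 7.38 on wild-type HSC arrays 66 and 67, 5.52 on wild-type array 75, and 5.42, 5.53 and 5.51 on NFAT5-deficient arrays 64, 70 and 76. Without wild-type HSC array 75, 3 lists passed: neutrophil and granule genes (median -0.44, adjusted p = 0.00179), G1/S and replication genes (0.26, 0.0128) and type I interferon-stimulated genes (0.25, 0.0150). That fit used the preset correlation alone. With all arrays, 0 of 28 lists passed with camera, with an estimated correlation or with fry. The median of the interferon-stimulated genes ran from 0.01 without NFAT5-deficient HSC array 70 to 0.25 without wild-type array 75, so the shift depended on single arrays. Without wild-type array 67 the neutrophil median shrank to -0.09 and the G1/S median turned to -0.02. The G1/S median was 0.10 without NFAT5-deficient HSC array 64 and 0.28 without array 76. The fit without wild-type array 75 also called 3 genes, against 2 without wild-type array 66 and 1 without NFAT5-deficient array 64.

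The single genes with the smallest p in HSC, given as values that did not pass, were Zfp799 (2.79), Qtrt2 (2.62), Scap (2.19), the sterol-sensing escort protein gene, Lrrfip1 (1.09), Mpped2 (0.69) and Slc16a6 (4.26) among those higher. Among those lower they were Vta1 (-1.42), Klf12 (-1.86), Gbf1 (-2.26), Pnpla2 (-2.43), the adipose triglyceride lipase gene, Smarce1 (-1.18) and Ercc6l2 (-2.64). Slc16a6 read 5.01 in wild-type HSC, within the range of the Y-linked genes, so the size of its rise is not resolved. Zfp799 (5.19) and Mpped2 (5.25) in wild-type HSC lay just above that range, so the size of their rises may not be resolved. The limma adjusted p of the single genes named ran from 0.573 to 0.669. The groups did not overlap for 10.2% of genes, where chance gives 10%.

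In MPP, 1 gene passed the test for loss of NFAT5 and was lower: Ms4a4c, a member of the membrane-spanning 4A family. It fell in MPP from a level of 7.30 ± 0.38 in wild-type to 5.26 ± 0.20 in NFAT5-deficient cells (SD, n = 3; difference -2.04, SE 0.20, limma adjusted p = 0.0124). The level in HSC was 5.27 ± 0.16 in wild-type and 5.04 ± 0.22 in NFAT5-deficient cells. All but the wild-type MPP level lay within or just above the range of the Y-linked genes, so the size of the fall may not be resolved. Genes with the next smallest p, none past the test, were Fcnb, a ficolin gene of myeloid cells (1.22), Gbf1, an exchange factor of Golgi transport (3.39), Epb41l3 (1.35), Rab2a (1.38), Rnf113a1 (1.84) and Postn (2.19) among those higher. Evi5l (-2.22), Odf2 (-1.79), Lrrc3b (-0.54), Ankdd1b (-0.62) and Prkg1 (-2.55) were the corresponding lower values. Evi5l in NFAT5-deficient MPP (5.20) and Fcnb in wild-type MPP (5.11) also lay just above the range of the Y-linked genes. The size of their changes may not be resolved. Postn in wild-type MPP (4.37), and Lrrc3b (4.91) and Ankdd1b (4.51) in NFAT5-deficient MPP, lay within the range of the Y-linked genes, so the size of these differences is not resolved.

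limma called 1 gene (0 higher and 1 lower), with 7 at an adjusted p under 0.10 and 1043 at an unadjusted p under 0.05. After centring each array on its median the split was 2 higher and 1 lower, and after quantile normalization 1 higher and 1 lower. Ms4a4c lost its call without wild-type MPP array 75 (-2.06, adjusted p = 0.0986), when only the MPP groups were fitted (adjusted p = 0.431) and without the outlying HSC arrays (adjusted p = 0.0723). Over its alternatives the adjusted p ran from 0.00466 to 0.431. The count was also 4 without wild-type MPP array 66 or NFAT5-deficient MPP array 76, 3 without NFAT5-deficient MPP array 70, and 2 without NFAT5-deficient HSC array 64 or wild-type HSC array 66.

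No list passed in MPP (0 of 28 with camera, with an estimated correlation or with fry, and 4 at an unadjusted camera p under 0.05). The type I interferon-stimulated genes had a median of -0.07, with 14 members higher and 22 lower (camera adjusted p = 0.476), among them Oas2 at 1.43. Their median ran from -0.10 without wild-type MPP array 75 to 0.06 without wild-type MPP array 67, so its sign depended on single arrays. The median over all genes in MPP was also -0.07, so this list did not lie below the other genes. The interferon-gamma and GTPase genes had a median of 0.19, MHC class II genes 0.25 and G1/S and replication genes 0.11, each with camera adjusted p = 0.294. The interferon-gamma median shrank to 0.07 without NFAT5-deficient MPP array 70 and the MHC class II median to 0.13 without wild-type MPP array 66. Osmotic stress genes had a median of -0.23, with 8 of 10 lower (adjusted p = 0.476), and the taurine transporter gene Slc6a6 at -0.74. Adjusted over the list alone, Fcnb passed in the neutrophil list, the hexokinase gene Hk2 (1.33) in the glycolysis list, and Ccng1 (1.19), Pmaip1 (-0.44) and Sesn2 (-0.41) in the p53 target list. The G2/M genes had a median of 0.08 (adjusted p = 0.315), which turned to -0.05 without NFAT5-deficient MPP array 64 and passed at 0.28 (adjusted p = 0.0154) without array 70. The groups did not overlap for 12.6% of genes, where chance gives 10%.

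**Figure D3:**
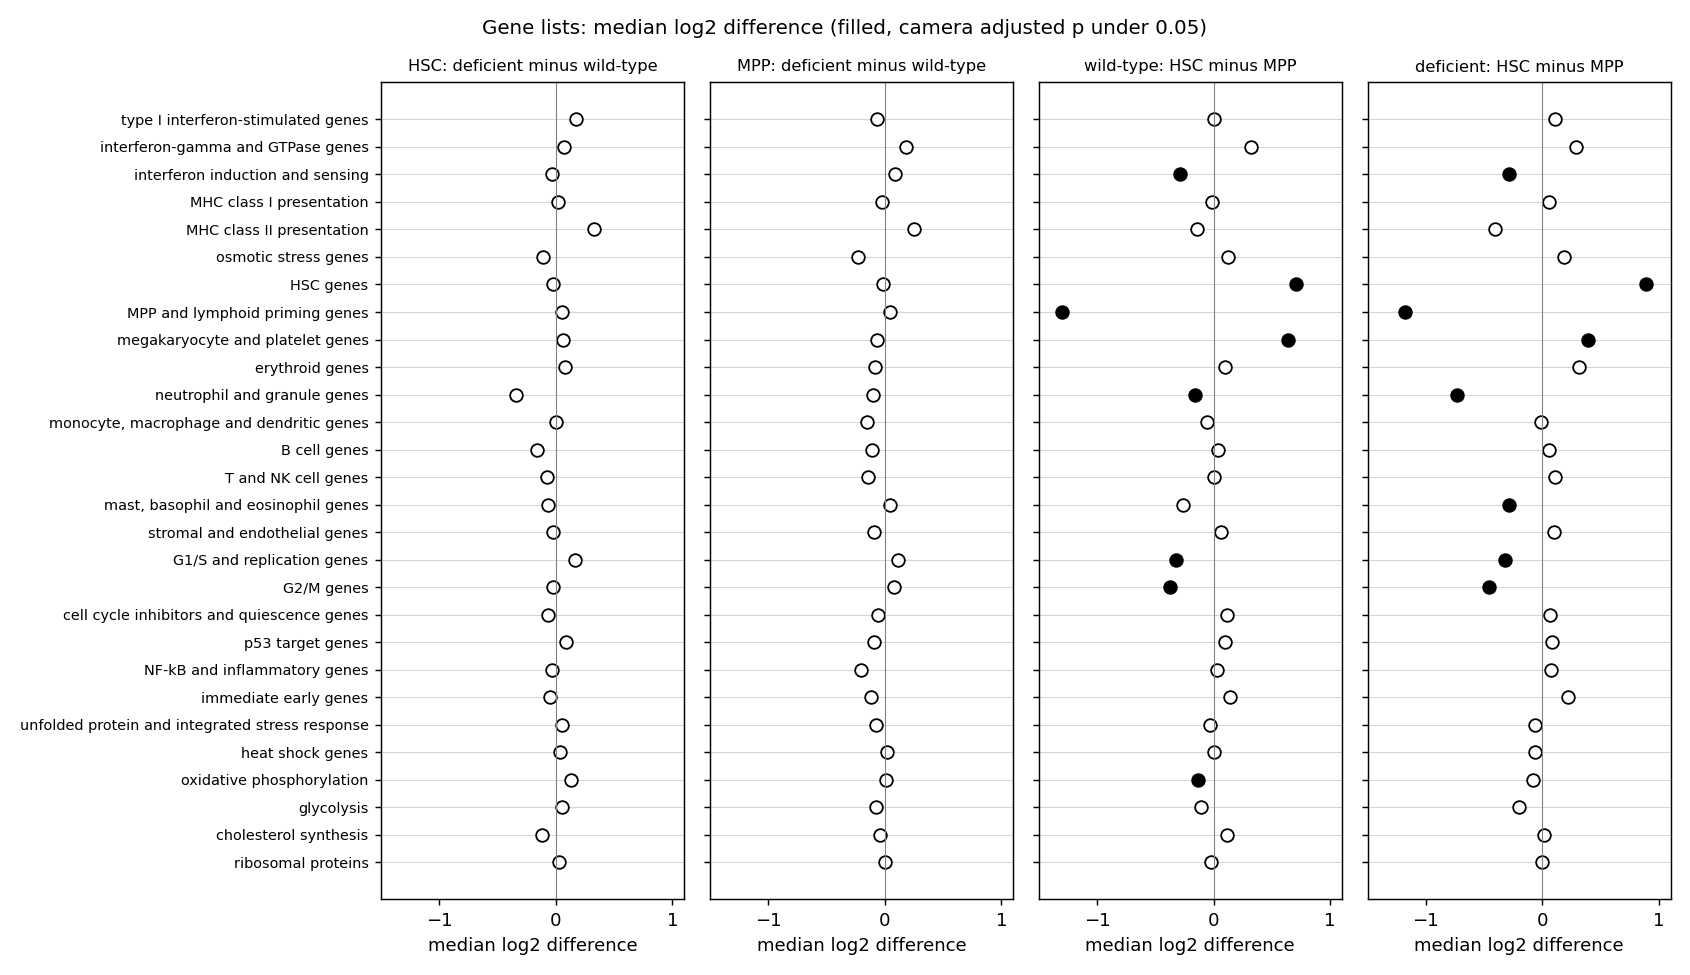
Median log2 difference (horizontal axes) of the 28 gene lists (vertical axis) in the 4 comparisons. Filled points, which passed camera at an adjusted p under 0.05, appear in the HSC minus MPP comparisons alone, 8 lists in each genotype.

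The difference between the NFAT5 effects in HSC and in MPP was tested as an interaction, and no gene passed. limma called 0 genes, with 817 at an unadjusted p under 0.05. There was 1 call without NFAT5-deficient HSC array 64, NFAT5-deficient MPP array 70 or wild-type HSC array 75. Gbf1 came closest, with an interaction of -5.65 (SE 0.63, adjusted p = 0.0549). Its level was 9.55 ± 0.39 in wild-type HSC, 7.28 ± 0.87 in NFAT5-deficient HSC, 6.39 ± 0.55 in wild-type MPP and 9.78 ± 0.37 in NFAT5-deficient MPP (SD, n = 3). It passed without NFAT5-deficient HSC array 64 (-5.15, adjusted p = 0.0393) and with dim genes left out (adjusted p = 0.0341), whereas without NFAT5-deficient MPP array 64 the adjusted p was 0.267. Other named values that did not pass were Ms4a4c (1.81, with NFAT5-deficient HSC at 5.04, within the range of the Y-linked genes), Adk (2.99), Stk39 (4.29), Prkg1 (3.68), Rab2a (-1.58) and Tle3 (-2.21). Of the lists, 0 passed, and the neutrophil and granule genes had the smallest p (median -0.26, adjusted p = 0.183). They passed without wild-type HSC array 75 (-0.61, adjusted p = 0.00260), wild-type MPP array 67 (-0.46, 0.0133) or NFAT5-deficient MPP array 76 (-0.33, 0.0327), and shrank to -0.02 without wild-type HSC array 67. Those fits used the preset correlation alone, and with all arrays 0 lists passed with an estimated one. Across all genes, the NFAT5 effects in HSC and in MPP correlated at a Pearson r of 0.0790.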

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

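The test by array number, the separate readings of Ms4a4c, Gbf1 and Evi5l and of Rab2a, and the count of opposite directions were chosen after the results were seen. So were the choice to list genes by that count and the readings of low-copy loss, of poor arrays and of replicates that agree by chance as open. Named genes are listed here where all 3 NFAT5-deficient arrays lay above all wild-type arrays in 1 population and below them in the other. That happened for 81 of 19494 genes, where chance gives 97.47, while 156 separated the same way in both populations against the same 97.47. The interaction passed for 0 genes over all genes tested. Adjusted over the 56 genes called in any comparison alone, 15 interactions passed, but those genes were picked on comparisons that share the interaction's arrays.

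Gbf1 was lower in NFAT5-deficient HSC and higher in NFAT5-deficient MPP, with an interaction of -5.65 on the log2 scale (limma adjusted p = 0.0549). Fcnb had an interaction of -1.55 (adjusted p = 0.204) and read 5.40, 5.06, 5.11 and 6.33 in wild-type HSC, NFAT5-deficient HSC, wild-type MPP and NFAT5-deficient MPP. Adk, the adenosine kinase gene, went the opposite way with 2.99 (adjusted p = 0.303). Postn had -2.92 (adjusted p = 0.571). The nuclear pore gene Nup160 had -2.78 (adjusted p = 0.634). Zc3h7a had 1.78 (adjusted p = 0.739). Tle3, a transcriptional corepressor gene, had -2.21 (adjusted p = 0.739). Stk39 had 4.29 (adjusted p = 0.780). Cd3g, at group means between 3.96 and 4.29, had -0.46 (adjusted p = 0.999). The endoplasmic reticulum gene Sdf2l1 had -0.91 (adjusted p = 0.999). Fcnb in NFAT5-deficient HSC, Postn in wild-type MPP (4.37) and NFAT5-deficient HSC (4.49), and Cd3g in every group lay within the range of the Y-linked genes, so the size of their interactions is not resolved.

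The primary granule genes Mpo, Elane and Ctsg were lower in HSC than in MPP, with Prtn3 nearly level (8.01 and 8.15 in wild-type cells), and mature neutrophil genes had lower values in NFAT5-deficient than in wild-type HSC, though their list did not pass. Mature neutrophils in the MPP gate are argued against as the whole source of the first difference: primary exceeded mature genes by 2.05 log2 units more in MPP than in HSC (6 against 6 arrays, exact permutation p = 0.00216, the smallest possible), and wild-type HSC array 67, with the highest mature mean of all arrays (7.38), had a primary mean of 7.45 where the MPP arrays had 9.21 or more. Mature genes were themselves higher in MPP by 0.47 (exact permutation p = 0.247), with all 3 NFAT5-deficient MPP arrays (6.49, 6.62 and 6.01) above the HSC arrays (5.42, 5.53 and 5.51), so some neutrophil RNA there stays open. The mature mean took in genes that were low in every group, such as Lcn2 (group means 5.11 to 5.63) and Mmp9 (5.66 to 5.77). These can hold its difference down, so the 2.05 depends in part on which genes stood for mature neutrophils. Both permutation tests mixed the genotypes and counted arrays that share a number as separate samples. For the second difference, mature neutrophil RNA that differs between animals may be a source: the mature gene mean correlated between HSC and MPP of 1 array number at a Pearson r of 0.803 (6 numbers, exact permutation p = 0.103; Spearman 0.771, p = 0.103). Without wild-type 66 and 67 the r was -0.369, so the relation rests on those numbers, the labels do not say that a number is an animal, and this source and an effect of genotype cannot be told apart.

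Replicates of 1 group differed by over 3 log2 units at 425 genes in wild-type HSC, 259 in NFAT5-deficient HSC, 242 in wild-type MPP and 149 in NFAT5-deficient MPP. A few poor arrays were argued against by the bound set beforehand. Leaving out wild-type HSC arrays 66 and 67 lowered the median within-group SD of genes in the middle tercile by level by 3.54%. For brighter genes below the top decile it fell by 8.94%. That test cannot decide: the wild-type HSC group then no longer entered the SD, and a median hardly responds to the genes counted above. Such genes also occurred in the other groups, so arrays 66 and 67 cannot account for all of them. By the bound set beforehand, random loss of low-copy transcripts from picogram input was argued against, since the middle tercile had only 0.729 times the median SD of the top decile. After that value was seen the bound was judged a poor one and this explanation left open, because the middle tercile lay at 5.90 to 7.36 and had an SD of 0.246, whereas the SD reached 0.554 in the decile below the top one and 0.337 in the top decile. No biological explanation was tested.

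Ms4a4c, Gbf1, Rab2a and Evi5l had values in wild-type MPP apart from those in NFAT5-deficient MPP and in wild-type HSC. By the bound set beforehand, replicates that agree by chance are argued against, since the median percentile of the within-group SD of all 4 among genes nearest in level was 59.4. Read apart afterwards, Ms4a4c, Gbf1 and Evi5l lay at 71, 47.8 and 88 (median 71), whereas Rab2a lay at 5.8, so a chance agreement of its replicates may account for its small p. A change of MPP levels through NFAT5 deficiency stays open: the genotype comparison in MPP passed for Ms4a4c (limma adjusted p = 0.0124) and not for Gbf1 (0.0624), Rab2a (0.0741) or Evi5l (0.0965). The 4 genes were picked for their small p, which by itself favours chance differences.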

How the results depend on the processing

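The fit without both outlying HSC arrays was chosen after seeing the data. The number of arrays limits these results. Unless stated, the cause of a change was not tested. HSC and MPP arrays that share a number were not treated as pairs: their deviations correlated at -0.0137 to 0.0641, and for 2 of 6 numbers the own partner matched best. With the replicate block as a fixed term, HSC against MPP gave 5 genes in wild-type and 3 in NFAT5-deficient cells. With a random block, 1 gene and 1 list passed the interaction.

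The HSC genotype comparison called 0 genes under the other settings of the same threshold, 1205 at an unadjusted p under 0.05, and 0 to 3 with each array left out. For its lists the range was 0 to 3. In MPP, 0 genes passed with only the groups compared and without the outlying HSC arrays. With dim genes filtered out 0 passed as well, but Ms4a4c, at a mean of 5.72, was then not among the genes tested. There were 3 after centring, 2 after quantile normalization, 6 with array weights, 7 at an adjusted p under 0.10, 1043 at an unadjusted p under 0.05, and 0 to 4 with each array left out. Its lists ranged from 0 to 1. The interaction gave 1 gene with dim genes filtered out, where fewer genes were tested, 1 at an adjusted p under 0.10, 817 at an unadjusted p under 0.05, and 0 to 1 with each array left out, as did its lists.

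HSC against MPP in wild-type gave 9 genes with only the groups compared, where fewer arrays set the spread, 18 without the outlying arrays, 72 at an adjusted p under 0.10, 1734 unadjusted, and 11 to 30 with each array left out. Its lists numbered 4 with an estimated correlation, 5 with fry, and 5 to 10 with each array left out. Neutrophil and granule genes also lost their call after centring and without both outlying arrays. Oxidative phosphorylation and interferon sensing genes lost theirs with dim genes filtered out, and oxidative phosphorylation genes after quantile normalization too. In NFAT5-deficient cells the genes numbered 23 with robust eBayes, 12 with only the groups compared, 24 after quantile normalization, 23 without the outlying arrays, 62 at an adjusted p under 0.10, 1540 unadjusted, and 5 to 32 with each array left out. The Nfat5 difference in MPP ran from -0.90 to -0.52 with each array left out, and its single limma test passed an unadjusted p of 0.05 without NFAT5-deficient array 76 or wild-type array 75.

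List medians, whose sign can differ from the direction of the camera test, turned in 6 of the 33 list results examined without pooling. The 33 were lists with an unadjusted camera p under 0.05 and, in every comparison, the type I interferon-stimulated genes. The only called one that turned was that of the neutrophil and granule genes in wild-type HSC against MPP (0.0980 without MPP array 67 and 0.136 without HSC array 75). The others were the G1/S genes by genotype in HSC (-0.0221 without wild-type array 67), the G2/M genes in MPP (-0.0535 and -0.0311 without NFAT5-deficient arrays 64 and 76), and the type I interferon-stimulated genes by genotype in MPP (0.0568 without wild-type array 67), in the interaction (-0.0252 without wild-type HSC array 67) and in wild-type HSC against MPP (0.00217, from -0.200 to 0.0780). Outside the 33, medians by genotype in MPP also turned. That of the MPP and lymphoid priming genes went from 0.0414 to -0.0365 without NFAT5-deficient MPP array 64. That of the HSC genes went from -0.0152 to 0.0248 without wild-type MPP array 66.

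The camera direction turned for 1 list, which was not called. That of the type I interferon-stimulated genes, HSC against MPP in NFAT5-deficient cells, turned upward with dim genes filtered out (median 0.172), after quantile normalization (0.0490) and after centring (0.0459). It also turned without NFAT5-deficient MPP or HSC array 76, and over the fits with each array left out the median ran from 0.0294 to 0.207. Single genes that turned were not called either. Without both outlying arrays, Ctss by genotype in HSC read 0.0487, Col3a1 in HSC 0.173 and the H2-Eb1 interaction -0.220. With single arrays left out, Col3a1 by genotype in HSC ran from -0.436 to 0.0632, Sparc in MPP from -0.0837 to 1.23, and Uty in HSC against MPP of NFAT5-deficient cells from -0.0995 to 0.00183.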

Other observations

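The fits that pool genotypes or populations, and the counts of other splits for the 5 comparisons that pool nothing, were chosen after the results were seen. With genotypes pooled, HSC differed from MPP at 119 genes, 58 higher and 61 lower (limma). They added genes that neither genotype passed alone: Mecom (1.60, adjusted p = 0.0257) and Mllt3 (1.87, adjusted p = 0.00847) rose in HSC, as did Aldh1a1 (1.91) and Mycn (1.37). Lower in HSC were Mpo (-3.71), Il1r1 (-3.01), Tyrobp (-2.12), Sting1 (-1.21) and Cd34 (-1.07). These names, chosen after their values were seen, come from a count that fell to 71 without NFAT5-deficient MPP array 76, 74 without wild-type MPP array 67, 76 without NFAT5-deficient MPP array 64 and 77 without wild-type MPP array 75.

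With populations pooled, 0 genes passed for loss of NFAT5 (limma, 1386 at an unadjusted p under 0.05), and Ms4a4c had the smallest adjusted p (-1.13, adjusted p = 0.123). Without wild-type HSC array 66, 2 genes passed. Of the lists, G1/S and replication genes rose (median 0.14, camera adjusted p = 0.0121; adjusted p = 0.169 with an estimated correlation). That call was lost without NFAT5-deficient HSC array 64 (median 0.09, adjusted p = 0.0681), with dim genes filtered out (adjusted p = 0.0948), after quantile normalization (adjusted p = 0.267) and without both outlying HSC arrays (adjusted p = 0.0597). Type I interferon-stimulated genes did not pass (median 0.11, camera adjusted p = 0.0630, and 0.169 with an estimated correlation). At the preset correlation they did in 5 of 12 fits with an array left out: NFAT5-deficient MPP 64 (adjusted p = 0.0298) or HSC 76 (0.0430), or wild-type MPP 66 (0.0475), MPP 67 (0.0312) or HSC 75 (0.0190). Over the 12 fits their median ran from 0.06 to 0.17. Interferon-gamma and GTPase genes passed in 3 of these fits, and MHC class II and oxidative phosphorylation genes in 2 each. With all arrays each of these lists had camera adjusted p = 0.0687. The interferon-gamma median turned to -0.05 without both outlying HSC arrays. HSC and MPP arrays counted as separate samples in these fits.

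Other splits of the arrays were tested for each count. With 6 arrays there are 10 splits, too few for a share under 0.05. In HSC the real genotype split gave 0 genes, which all 10 splits reach by definition, and the highest other 5. In MPP the real split gave 1 gene and the highest other 0 (1 of 10). For HSC against MPP the real split gave 32 genes in wild-type and the highest other 2 (1 of 10), and 41 in NFAT5-deficient cells with the highest other 1 (1 of 10). With genotypes pooled, the real split gave 119 genes and the highest other 3, with calls in 17 other splits. Only the real one of 100 splits reached 119, the smallest share that 100 splits allow. Chance is thus unlikely but not excluded, and arrays that share a number counted as separate samples. For the interaction and for loss of NFAT5 with populations pooled the real count was 0, which all 100 splits reach by definition (highest other 2 in each), so these splits decide nothing.

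Among the 2615 probe sets without a gene name, limma called 0 in each comparison, with 148 at an unadjusted p under 0.05 in HSC by genotype and 139 in MPP by genotype.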
